A study of Mus musculus with 15 samples.

How the data were processed

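Bulk RNA sequencing of brain cortex was analysed in 15 male C57BL/6J mice, 1 library per mouse, in 3 groups of 5. Per the labels, control mice received control food, depleted mice received food with PLX3397 for 9 days, and mice of the repopulation group received PLX3397 food for 9 days and then control food for 9 days. PLX3397 is an oral inhibitor of CSF1R, the receptor tyrosine kinase whose signal keeps microglia alive. Each library therefore came from a separate animal, and the spread between libraries includes the spread between mice.

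The deposited table holds raw counts of reads per gene, as whole numbers, for 53278 gene symbols. Per the submitters' processing notes, FastQC, MultiQC, STAR, DESeq2 and DESeq were used, with the mm10 mouse genome. The notes give these names without roles or versions, and the counting tool, the gene annotation release and the use of strand are not given in the sources used here. Column names were matched to the labels by group and mouse number, and no column was left unmatched. Total counts per library ran from 23413551 to 48617851, so that a gene at 1 CPM (a read count scaled to the library total) rests on 23.4 to 48.6 reads per library. These totals limit mainly the genes near or below that level. No pair of libraries held identical values, and the counts of libraries of the same group differed by more than sampling noise, with chi-square values of 2.53 to 9.95 per degree of freedom over genes with at least 20 counts.

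Changes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by the filterByExpr rule, which left 18369 genes, libraries were scaled with TMM factors, and the quasi-likelihood F test with robust dispersion was run on the deposited counts of all 15 libraries at once, so that the 3 groups shared 1 estimate of the spread. No covariate was used, since the labels name no batch. Adjusted p-values are Benjamini-Hochberg values over all 18369 genes, with a threshold of 0.05, and log2 fold changes carry the standard error (SE) of that fit. Values per group are the mean CPM with the standard deviation (SD) over 5 mice. A gene with 0 counts in a whole group is given as a lower bound on the fold, computed against a floor of 3 counts over that group, which covers counting error only. Exact two-sided permutation tests compared 5 with 5 libraries over all 252 splits, so that 0.00794 is the smallest p they can give.

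Before the data were examined, 33 gene lists with 474 entries (464 distinct genes) were fixed. They cover homeostatic microglia, pan-myeloid genes, microglia activation, border macrophages, blood leukocytes, erythroid cells, the interferon response, MHC class I with antigen processing, MHC class II, proliferation, purinergic and ectonucleotidase genes, vascular tone, smooth muscle, pericytes, endothelium, fibroblasts and meninges, astrocytes, reactive astrocytes, oligodendrocyte precursors, oligodendrocytes and myelin, excitatory neurons, inhibitory neurons, synapses, immediate early genes, cholesterol biosynthesis, cytokines and CSF1R ligands, the glucocorticoid response, circadian genes, striatum, hippocampus, choroid plexus, heat shock and mitochondrially encoded genes. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 32 lists that had tested genes. None of the 16 blood leukocyte genes, 0 in all, passed the count filter, so that list was not tested. The same test with an estimated correlation, and fry, were run beside it. Fry tests a list's genes without setting them against the other genes, and its values are given for some lists only. Each list's median log2 CPM, less the control mean, gave a score per library.

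The genes named in the text follow a rule that was also fixed before the data were examined. It takes Csf1r, Cx3cr1, P2ry12, Tmem119, Entpd1, Nt5e, Adora1 and Adora2a. In each comparison it adds the 8 higher and 8 lower genes with the largest fold change among those called, at a mean CPM of at least 1 and without predicted gene models. It also adds the 6 higher and 6 lower genes with the smallest adjusted p outside the 4 microglial and macrophage lists, and up to 3 genes with the smallest adjusted p in each list. Exceptions are said to be chosen later where they appear. Some genes that the rule selects are not reported here.

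Gene coordinates, exon lengths and GC content came from GENCODE release 21 for mouse on the GRCm38 assembly, which is mm10, joined by symbol. This annotation held 49721 of the symbols (93.3%), and 97.8% of the tested genes had a length and a GC value. Since the use of strand is not given, counts of genes that overlap another gene are uncertain. Among the named genes this concerns Csf1r with Hmgxb3, P2ry12 and P2ry13 with Med12l, Cx3cr1 with several neighbours and Itgam with a predicted gene on its own strand. The complement, histocompatibility and interferon-induced families hold close paralogs, so their single members are less certain than the lists.

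The alternatives fixed before the data were examined were a DESeq2 1.42.0 Wald test, DESeq2-type size factors, no filter on low counts (36695 genes), a filter of CPM of at least 1 in at least 5 libraries (15541 genes), a fit of only the 2 groups compared, the mouse number as a block, limma voom, 1 surrogate variable from sva 3.50.0, split controls, the mean in place of the median for the microglial share and leaving out each library in turn. Chosen after seeing the data were the removal of smooth trends of each library on exon length and GC content (fitted with mgcv 1.9.3), the removal of 2 libraries in doubt together, an exact permutation test of the list scores, and the overlap of effects outside the 4 microglial and macrophage lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

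The comparisons with control share the same 5 control libraries, so their fold changes are correlated by chance. This was measured with 20 simulated pairs of unchanged groups and with 10 splits of the controls into 2 and 3 libraries. The steps were also tested on simulated counts drawn from the real means and library sizes. For depletion versus control, edgeR recovered 55.2% of 67 genes changed 1.25-fold, 86.6% of 67 changed 1.5-fold and 93.9% of 66 changed 2-fold, with 12 false calls among 18029 genes. For repopulation versus control the shares were 61.2%, 77.6% and 98.5% with 13 false calls, and for repopulation versus depletion, where both sets of changes meet, 61.2% of 134, 86.6% of 134 and 97.7% of 132 with 15 false calls. The false calls were 7.1%, 7.6% and 4.39% of all edgeR calls in the 3 comparisons. In DESeq2 on the same counts they were 13.8%, 12.1% and 9.21%. With no gene changed, 1, 1 and 0 genes of 18011 were called in these 3 comparisons. The list test called 3 of 3 raised lists and 0 of 27 others for depletion versus control. The simulated genes were drawn independently of each other, whereas the estimated correlation in the real data was 0.64 for myelin genes and 0.483 for precursor genes. The 0 of 27 therefore gives no measure of false list calls in the real data. A microglial share set to 5% came back as 4.71%. A simulated length trend of 0.15 log2 units per doubling in repopulation versus control gave 3479 false calls among 17983 genes before the trends were taken out and 13 after. It was steeper than the real difference (mean slopes of -0.0494 in control and 0.0523 after repopulation). It was also the same in all repopulation libraries and held no GC trend. These 2 counts therefore do not measure the false calls in the real data, before or after the correction.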

Results

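The data were read counts per gene from the cortex of 15 mice, 5 on control food, 5 on food with the CSF1R inhibitor PLX3397 for 9 days, and 5 returned to control food for 9 days after 9 days of PLX3397. Microglia are the resident macrophages of the brain and depend on CSF1R. The title of the series names microglia, the reactivity of brain vessels and the ectonucleotidase CD39, the product of Entpd1. Total counts per library were 24347802 to 48617851 in control, 23413551 to 29482140 on PLX3397 and 26837517 to 29582274 after repopulation. In a principal component analysis of log2 CPM, the first component held 40.4% of the variance. It set the 5 PLX3397 libraries (38.9 to 40.0) apart from the controls (-18.6 to -16.3) and the repopulation libraries (-23.4 to -20.6), which did not overlap each other either.

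The first comparison, PLX3397 against control, asks what is lost from the cortex when microglia are depleted. The transcripts that define microglia were nearly absent on PLX3397. Csf1r, the receptor that PLX3397 inhibits, was at 84.9 ± 4.09 CPM in control mice and 0.216 ± 0.12 CPM on PLX3397 (SD, n = 5 each), 0.254% of the control level. Cx3cr1, the fractalkine receptor, was at 46.4 ± 4.44 and 0.106 ± 0.0875 CPM, P2ry12, the ADP receptor of resting microglia, at 24.5 ± 1.61 and 0.726 ± 0.124 CPM, and Tmem119, a microglial membrane protein, at 19.1 CPM and 5.79% of that. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were -8.58 (SE 0.10, adjusted p = 6.1e-28) for Csf1r, -8.77 (adjusted p = 4.27e-22) for Cx3cr1, -5.07 (adjusted p = 8.04e-24) for P2ry12 and -4.09 (adjusted p = 3.08e-20) for Tmem119. On GRCm38, Csf1r lies on chromosome 18 from 61100598 to 61132149, Cx3cr1 on chromosome 9 from 119901616 to 120069879, P2ry12 on chromosome 3 from 59216272 to 59262871 and Tmem119 on chromosome 5 from 113793729 to 113800516, all annotated as protein-coding genes. Csf1r overlaps Hmgxb3, P2ry12 overlaps Med12l and Cx3cr1 overlaps several genes, among them Wdr48, so the origin of their few remaining reads is uncertain.

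**Figure D1:**
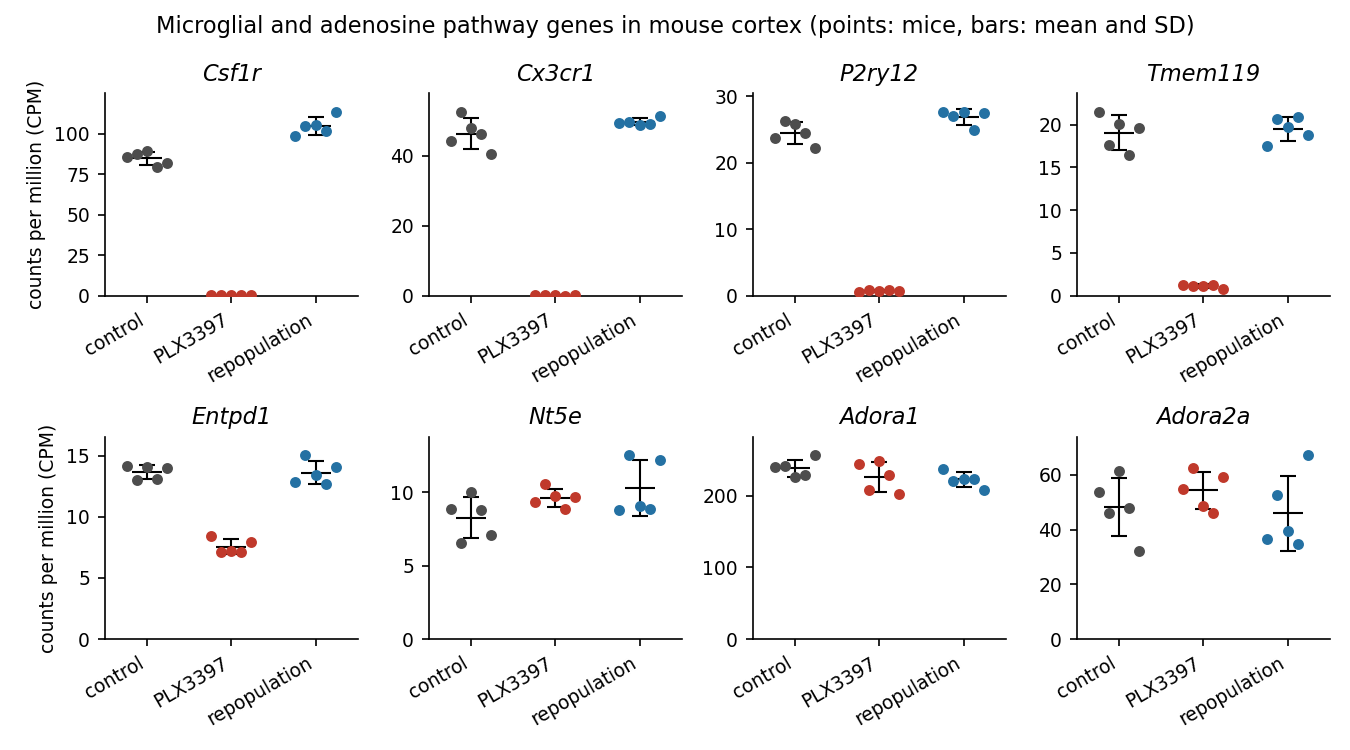
CPM of 8 genes in each of the 15 cortex libraries, 5 per group, with points for mice and bars for the mean and SD. Csf1r, Cx3cr1, P2ry12 and Tmem119 lie near 0 on PLX3397 and at or above the control level after repopulation, and Entpd1 falls from 13.7 to 7.57 CPM and is at 13.6 CPM after repopulation.

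All 17 homeostatic microglia genes fell on PLX3397 (17 adjusted over the list alone), with a median log2 fold change of -5.04, and so did all 34 pan-myeloid genes (34 adjusted over the list alone), with a median of -4.44, which stays the same with Itgam at its lower bound. The median homeostatic gene was left at 3.25% ± 0.514 of the control mean (SD, n = 5, range 2.47 to 3.85) and the median pan-myeloid gene at 4.84% ± 0.567. The controls measured the same way stood at 98.9% ± 4.7 and 100.2% ± 3.45 (exact permutation p = 0.00794 for each, the smallest that 252 splits allow). Of the 51 genes of both lists, 16 were left at under 1% of control, 15 at 1 to 10%, 14 at 10 to 25% and 6 above 25%, the highest being Blnk, a B cell linker protein named here after its value was seen, at 69.7%. The complement genes C1qa, C1qb and C1qc, which tag synapses and debris, fell by 8.31, 8.32 and 8.23 on the log2 scale. Fcrls, an Fc receptor-like gene (log2 fold change -8.35), the lectin gene Siglech (-7.48) and the lysosomal gene Laptm5 (-6.08) fell as well. Itgam, the integrin subunit CD11b, had 0 counts in all 5 PLX3397 libraries against 5.78 ± 0.784 CPM in control, at least 269-fold lower, and Tlr13, a receptor for bacterial RNA, had 0 against 2.20 ± 0.471 CPM, at least 101-fold lower. Outside the lists the smallest adjusted p-values among lower genes belonged to further myeloid genes. They included the pore-forming protein gene Mpeg1 (log2 fold change -4.66, adjusted p = 3.08e-20), the granulocyte colony-stimulating factor receptor gene Csf3r (-7.05), the checkpoint gene Vsir (-2.72), Arhgap45 (-5.41), Pld4 (-6.74) and the oxidase subunit gene Ncf1 (-4.72). Camera called the homeostatic list (adjusted p = 5.83e-40) and the pan-myeloid list (adjusted p = 3.35e-76), and both calls held with an estimated correlation (adjusted p = 1.78e-06 and 9.48e-08).

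Transcripts of macrophages at the borders of the brain fell as well, some of which microglia share. All 6 measured border macrophage genes fell (6 adjusted over the list alone), with a median log2 fold change of -3.64 (camera adjusted p = 4.55e-10, and 0.000592 with an estimated correlation). Stab1, a scavenger receptor, fell from 22.8 ± 1.79 to 2.31 ± 0.73 CPM (adjusted p = 1.78e-14), the mannose receptor gene Mrc1 (-5.74) to 1.76% of control and the coagulation factor gene F13a1 to 3.36%. Of the 5 MHC class II genes, which present antigen, 4 fell (5 adjusted over the list alone), among them Cd74 (-1.71, adjusted p = 2.12e-07), H2-Ab1 (-2.38) and H2-Aa (-2.07), with camera adjusted p = 2.78e-05 and 0.0153 with an estimated correlation. Of 10 MHC class I and antigen processing genes, 5 fell (8 adjusted over the list alone), led by B2m, the light chain of class I, from 57.7 ± 2.54 to 43.8 ± 3.64 CPM (-0.39, adjusted p = 4.5e-06) and the immunoproteasome gene Psmb8 (-1.01). This list was called with the preset correlation (camera adjusted p = 0.000176) and not with an estimated one (adjusted p = 0.0927), and 2 of its genes were lower with length and GC trends taken out. Of 15 microglia activation genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone). The chemokine gene Ccl6 (-3.80), the oxidase gene Cybb (-2.37) and the integrin gene Itgax (-2.04) fell, and the list's camera adjusted p of 0.0115 became an adjusted p of 0.235 with an estimated correlation and 0.0586 in the exact permutation test of list scores. Among 9 tested genes for cytokines and CSF1R ligands, 2 fell and 2 rose (camera adjusted p = 0.185, 2 and 2 adjusted over the list alone). Tgfb1, a growth factor on which microglia depend, fell from 5.48 ± 0.53 to 1.77 ± 0.324 CPM (-1.63, adjusted p = 6.25e-10), as did Il1a (-2.95).

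Entpd1, which encodes CD39, the enzyme that breaks down extracellular ATP and ADP, fell from 13.7 ± 0.557 to 7.57 ± 0.601 CPM on PLX3397 (SD, n = 5 each). Its log2 fold change was -0.86 (SE 0.07, edgeR adjusted p = 9.44e-10), with an exact permutation p of 0.00794 (0.0119 after Benjamini-Hochberg adjustment over 3 comparisons). More of Entpd1 was left than of the median microglial gene. Nt5e, which encodes CD73, the enzyme of the next step from AMP to adenosine, was at 8.27 ± 1.41 CPM in control and 9.64 on PLX3397 (0.22, adjusted p = 0.232). The adenosine receptor genes Adora1 (238 and 227 CPM, -0.07, adjusted p = 0.388) and Adora2a (48.2 and 54.3 CPM, 0.17, adjusted p = 0.647) were not called either. Entpd1 lies on chromosome 19 from 40612366 to 40741602, Nt5e on chromosome 9 from 88327197 to 88372092, Adora1 on chromosome 1 from 134199223 to 134235431 and Adora2a on chromosome 10 from 75316877 to 75334784. Of 23 purinergic and ectonucleotidase genes, 7 fell and 0 rose (7 and 0 adjusted over the list alone), among them the ADP receptor gene P2ry13 (-7.34), with camera adjusted p = 0.000176 and 0.0153 with an estimated correlation. P2ry12 and P2ry13 are also in the homeostatic microglia list, and the median of the purinergic list was -0.07 against a mean of -0.72. The list call is therefore not separate from the loss of microglial transcripts.

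Some genes of the vessel lists changed, while most members of these lists were not called. Bulk RNA does not tell which cells a change comes from, so a changed member need not mean a change in vessels. In the vascular tone list, 4 of 26 genes rose and 6 fell (5 and 8 adjusted over the list alone), without a call for the list (camera adjusted p = 0.587, downward, while its median was 0.02). Ptgs1, the cyclooxygenase that starts prostanoid synthesis, fell from 14.6 ± 1.12 to 8.89 ± 1.27 CPM (-0.72, adjusted p = 5.91e-07), the caveolin gene Cav1 fell (-0.42, adjusted p = 0.000259) and Gucy1b3, a subunit of the nitric oxide receptor, rose (0.17, adjusted p = 0.00184). Of 18 endothelial genes, 6 fell and 0 rose (9 and 0 adjusted over the list alone), among them Emcn (-0.74, adjusted p = 1.49e-05), Itm2a (-0.35) and the lipid transporter gene Mfsd2a (-0.32). Of 12 pericyte genes, 3 fell and 0 rose (5 and 0 adjusted over the list alone), including Rgs5 (-0.25, adjusted p = 0.000338) and Cspg4, which oligodendrocyte precursors also express. Camera called both lists (adjusted p = 0.000325 and 0.0074), and neither with an estimated correlation (adjusted p = 0.105 and 0.187), nor pericytes in the exact permutation test of list scores (adjusted p = 0.0586). Smooth muscle had 1 lower gene of 10 (1 adjusted over the list alone, camera adjusted p = 0.246), and the fibroblast and meninges list had 0 of 10 (0 adjusted over the list alone, adjusted p = 0.961).

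Oligodendrocyte precursor genes and myelin genes moved in opposite directions. Of 11 oligodendrocyte precursor genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone), with a median log2 fold change of -0.71. Matn4, a matrix protein of precursors, fell from 10.8 ± 1.32 to 3.74 ± 0.713 CPM (-1.54, adjusted p = 5.93e-11), the proteoglycan gene Cspg4 (NG2) from 24.0 ± 1.9 to 12.9 ± 1.43 CPM (-0.90, adjusted p = 1.51e-10) and the sialidase gene Neu4 by 1.42 on the log2 scale. Of 15 oligodendrocyte and myelin genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.27. The tight junction gene of myelin Cldn11 rose from 141 ± 5.54 to 193 ± 18.1 CPM (0.45, adjusted p = 1.78e-05), Mal rose by 0.49 (adjusted p = 0.000261) and Mag, the myelin-associated glycoprotein, by 0.26 (adjusted p = 0.00204). Camera called both lists (adjusted p = 2.41e-08 for precursors and 1.12e-07 for myelin), while neither was called with an estimated correlation (adjusted p = 0.105 and 0.235). Fry called both (adjusted p = 3.35e-05 and 0.00292). In exact permutation tests of the list scores per library, chosen after seeing the data, both differed from control (p = 0.00794, adjusted p = 0.0254 over 32 lists).

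C4b and Gfap, which astrocytes express, rose on PLX3397. C4b, a complement component that reactive astrocytes induce, rose from 20.7 ± 1.91 to 47.2 ± 5.43 CPM (1.19, adjusted p = 1.79e-05) on PLX3397. Gfap, the filament protein of astrocytes, rose from 159 ± 24.3 to 260 ± 23.8 CPM (0.71, adjusted p = 0.000226). As lists, neither astrocyte genes (2 higher and 1 lower of 15, and 2 and 1 adjusted over the list alone, camera adjusted p = 0.722) nor reactive astrocyte genes (2 higher and 1 lower of 14, 4 and 2 adjusted over the list alone, adjusted p = 0.48, upward while the median was -0.11) were called. Btbd16 (0.83), the growth factor gene Egf (0.67) and Ror1 (0.67), a receptor of Wnt signalling, rose too. Sytl5 (0.76), the topoisomerase gene Top2a (0.72) and the kinesin gene Kif18a (0.66) were called at adjusted p = 0.0374, 0.0407 and 0.0371. Each of these calls was lost when any of 7, 7 and 6 single libraries was left out (adjusted p up to 0.093 without depletion 5, 0.103 without control 1 and 0.107 without control 3). In the proliferation list, 4 of 27 genes rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0513). The smallest adjusted p-values among all higher genes belonged to small changes. They included Fam214a (0.45, adjusted p = 3.1e-08), the helicase gene Dhx9 (0.31), the deubiquitinase gene Usp33 (0.32), Dmxl2 (0.33), which acts in acidifying synaptic vesicles, and the cadherin gene Cdh2 (0.31).

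Of 18 immediate early genes, which neuronal activity induces, 5 fell and 0 rose (5 and 0 adjusted over the list alone). Nptx2, a pentraxin that clusters glutamate receptors, fell from 73.7 ± 3 to 51.2 ± 5.01 CPM (-0.53, adjusted p = 1e-06), Bdnf, a neurotrophin, by 0.38 and Egr4 by 0.54 on the log2 scale. Of 18 cholesterol biosynthesis genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), among them Lss, the lanosterol synthase gene (0.27), and the sterol carrier gene Stard4 (0.27). Camera called both lists (adjusted p = 0.000394 and 0.000497), and neither with an estimated correlation (adjusted p = 0.398 and 0.38), nor immediate early genes in the exact permutation test of list scores (adjusted p = 0.224). No neuronal list was called. Excitatory neurons had 1 lower gene of 9 (1 adjusted over the list alone, adjusted p = 0.306). Inhibitory neurons had 1 higher and 5 lower of 12 (2 and 5, adjusted p = 0.235), with Pvalb, the calcium buffer of fast-spiking cells, lower (-0.32, adjusted p = 0.00133). Synapses had 3 higher of 11 (3, adjusted p = 0.386). Interferon response genes had 2 lower of 26 (2 adjusted over the list alone, camera adjusted p = 0.0581), namely Trim30a (-0.78) and Ifi204 (-2.49). Glucocorticoid response genes had 2 lower of 10, led by the cell cycle inhibitor gene Cdkn1a (-0.39), circadian genes 1 higher and 2 lower of 12 and heat shock genes 1 lower of 6, none called as a list (camera adjusted p = 0.235, 0.235 and 0.386). The erythroid list (0 of 3, adjusted p = 0.235, and 0.0418 without control 5) and the mitochondrially encoded list (1 higher of 11, adjusted p = 0.708) were not called either.

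Markers of neighbouring tissue were measured beside these groups. Choroid plexus genes had a median log2 fold change of 1.52 (0 of 8 called, camera adjusted p = 0.073), with Ttr, the transthyretin gene, at 72.0 ± 72.1 CPM on PLX3397 against 7.11 ± 6.07 CPM in control. Striatum genes had a median of 0.22 (0 of 11, adjusted p = 0.0852) and hippocampus genes 0.03 (0 of 5, adjusted p = 0.386). Some of the lists that were not called passed the threshold when single libraries were left out. Choroid plexus genes did so, upward, without any of 9 libraries (lowest adjusted p = 0.00577, without repopulation 4), and proliferation genes, upward, without any of 8 (0.0122, without depletion 4). Interferon response genes did so, downward, without any of 5 (0.00438, without depletion 4), and striatum genes, upward, without any of 3 (0.0117, without control 3). With length and GC trends taken out, interferon response genes were called downward (adjusted p = 0.0173), and proliferation and striatum genes upward (0.0467 for each). Under that correction the counts of higher and lower genes were 1 and 2 for astrocytes, 1 and 2 for inhibitory neurons, 1 and 1 for synapses, 2 and 0 for proliferation and 4 and 1 for mitochondrially encoded genes.

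In total 1505 genes were higher and 1533 lower on PLX3397 than in control among 18369 tested (edgeR, Benjamini-Hochberg). Of these, 19 and 280 changed by at least 1 log2 unit, and the median absolute log2 fold change of the called genes was 0.19 for higher and 0.28 for lower ones. Camera called 13 of 32 lists, and 5 with an estimated correlation. Many of the small changes lay along gene properties. The slope of log2 CPM on exon length per doubling was -0.0494 ± 0.0137 in control and -0.0029 ± 0.0259 on PLX3397 (SD, n = 5, exact permutation p = 0.0238), and the slope per 10 points of GC was 0.0562 ± 0.0147 and -0.0372 ± 0.0233 (exact permutation p = 0.00794). With these trends taken out, an alternative chosen after seeing the data, 1036 genes were higher and 1028 lower, of which 755 and 849 were called both ways.

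**Figure D2:**
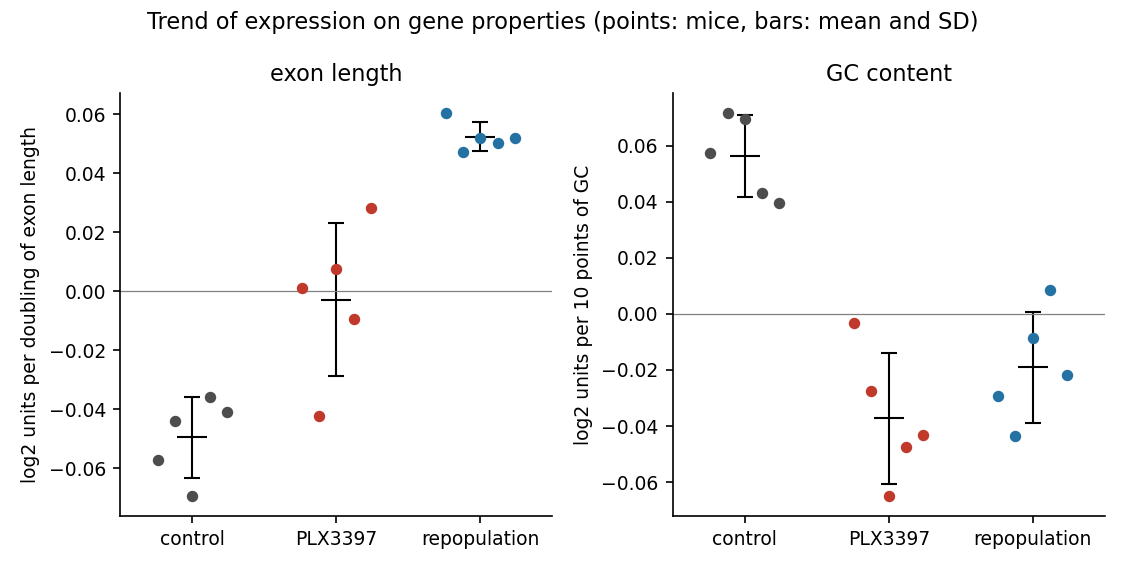
Slopes of log2 CPM on exon length (left, log2 units per doubling) and GC content (right, log2 units per 10 percentage points) in each library, with points for mice and bars for the mean and SD of 5. The length slopes average -0.0494 in control, -0.0029 on PLX3397 and 0.0523 after repopulation.

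The second comparison, repopulation against PLX3397, asks what came back after 9 days without the inhibitor. Microglial transcripts came back. Csf1r was at 105 ± 5.47 CPM, Cx3cr1 at 49.8 ± 0.969, P2ry12 at 26.9 ± 1.18 and Tmem119 at 19.5 CPM, with log2 fold changes over PLX3397 of 8.88 (adjusted p = 1.87e-28), 8.88 (adjusted p = 2.87e-22), 5.20 (adjusted p = 3.65e-24) and 4.12 in edgeR's test. Of 17 homeostatic genes 16 rose (17 adjusted over the list alone), and of 34 pan-myeloid genes 33 rose (34 adjusted over the list alone), with medians of 4.57 and 4.73 and camera adjusted p = 1.83e-39 and 1.17e-78 (1.9e-06 and 7.88e-08 with an estimated correlation). The sialic acid receptor gene Cd33 rose by 8.43, C1qc by 8.37, C1qb by 8.24 and Ctss, a lysosomal protease gene, by 8.23. Itgam was at least 295-fold and Tlr13 at least 128-fold higher than on PLX3397, where both had 0 counts. Outside the lists Mpeg1 (5.49), Csf3r (7.71), Arhgap45 (5.68), Vsir (2.73), Pld4 (7.39) and the exchange factor gene Fgd2 (3.49) rose. All 6 border macrophage genes rose (6 adjusted over the list alone, median 3.68, camera adjusted p = 2.24e-10, and 0.000542 with an estimated correlation), and Tgfb1 rose by 1.77 (adjusted p = 8.46e-11). In the cytokine and CSF1R ligand list, 2 genes rose and 1 fell.

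Entpd1 rose from 7.57 ± 0.601 to 13.6 ± 0.961 CPM after repopulation (0.85, SE 0.07, edgeR adjusted p = 1.03e-09, exact permutation p = 0.00794, adjusted p = 0.0119). Nt5e (0.09, adjusted p = 0.656), Adora1 (-0.03, adjusted p = 0.805) and Adora2a (-0.24, adjusted p = 0.502) were not called. In the purinergic list 6 of 23 genes rose, among them P2ry13 (7.37), and 1 fell, with camera adjusted p = 0.000509 and 0.0215 with an estimated correlation. This list shares P2ry12 and P2ry13 with the homeostatic list, and its median was 0.10 against a mean of 0.76. Ptgs1 rose from 8.89 to 16.7 ± 1.02 CPM (0.91, adjusted p = 4.8e-09) and Ednrb, an endothelin receptor gene, by 0.28 (adjusted p = 0.00187). Of 18 endothelial genes 8 rose and 2 fell (8 and 3 adjusted over the list alone), among them the organic anion transporter gene Slco1a4 (0.48), Emcn (0.62) and the angiopoietin receptor gene Tek (0.32). Of 12 pericyte genes 4 rose (5 adjusted over the list alone), including Cspg4, Notch3 (0.44) and Rgs5 (0.28). Camera called both lists (adjusted p = 0.0107 and 0.00925) but not with an estimated correlation (adjusted p = 0.226 and 0.167), and the endothelial call was also lost without depletion 5 (adjusted p = 0.0546) and in the exact permutation test of list scores (adjusted p = 0.113).

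Oligodendrocyte precursor and myelin genes moved back. Of 11 precursor genes 8 rose (9 adjusted over the list alone), with Cspg4 at 27.2 ± 1.02 CPM (1.08, adjusted p = 2.93e-12), Matn4 at 9.75 ± 0.556 CPM (1.39, adjusted p = 5.35e-10) and the proteoglycan gene Vcan higher by 0.74. Of 15 myelin genes 14 fell (14 adjusted over the list alone), with Cldn11 (-0.64, adjusted p = 1.41e-07), Mal (-0.58) and Cnp (-0.43), a phosphodiesterase of myelin. Camera called both (adjusted p = 1.08e-08 and 5.27e-10), which was lost with an estimated correlation (adjusted p = 0.0833 and 0.154). Gfap fell from 260 ± 23.8 to 162 ± 8.84 CPM (-0.69, adjusted p = 0.000297), Thbs4, a thrombospondin gene, fell by 0.68 and the metallothionein gene Mt1 by 0.54. The ferritin gene Fth1 (-0.33), Tpi1 (-0.32), Tspan2 (-0.43) and the proton pump gene Atp6v0d1 (-0.24) fell as well. Of 15 astrocyte genes 6 fell (6 adjusted over the list alone, camera adjusted p = 0.0337, and adjusted p = 0.469 with an estimated correlation). This call was also lost without depletion 1 (adjusted p = 0.111) or repopulation 1 (adjusted p = 0.0783) and in the exact permutation test of list scores (adjusted p = 0.0598). Of 27 proliferation genes 7 fell (7 adjusted over the list alone, camera adjusted p = 2.2e-05, and 0.033 with an estimated correlation). Top2a fell by 1.23 (adjusted p = 0.00163), the centromere gene Cenpf by 1.01, and the cycling marker gene Mki67 by 0.61 on the log2 scale.

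Interferon and antigen presentation genes rose as well. Of 26 interferon response genes 24 rose (25 adjusted over the list alone), with a median log2 fold change of 1.12 (camera adjusted p = 1.38e-19, and 0.019 with an estimated correlation). Ifit3, an antiviral effector gene, rose by 1.15 (adjusted p = 1.2e-08), Trim30a by 1.43 and Ifi204, a sensor of DNA, by 4.45. Of 10 MHC class I genes 8 rose (9 adjusted over the list alone, adjusted p = 5.68e-10, and 0.00744 with an estimated correlation), among them B2m (0.73) and H2-D1 (0.68). Of 5 class II genes 4 rose (4, adjusted p = 0.000708, and 0.035 with an estimated correlation), including Cd74 (1.37). Microglia activation genes had 6 higher and 1 lower of 15 (adjusted p = 0.00969, and adjusted p = 0.186 with an estimated correlation), with Itgax higher by 3.84. Cholesterol biosynthesis genes had 5 lower of 18 (6 adjusted over the list alone), among them Fdft1 (-0.29) and Msmo1 (-0.21), and heat shock genes 1 lower of 6, the chaperone gene Hspa8 (-0.40). Camera called these lists at adjusted p = 0.000808 and 0.0226, which became an adjusted p of 0.368 and 0.469 with an estimated correlation, and heat shock was also lost without depletion 1 (adjusted p = 0.072). The remaining lists were not called by camera, among them vascular tone (6 higher and 2 lower of 26, and the same adjusted over the list alone, adjusted p = 0.235), mitochondrially encoded genes (0 higher and 2 lower of 11, adjusted p = 0.136) and immediate early genes (0 of 18, adjusted p = 0.826). In the exact permutation test of list scores, vascular tone was called upward (0.0822 ± 0.0402 against -0.0503 ± 0.0743, adjusted p = 0.0195) and mitochondrially encoded genes downward (adjusted p = 0.0317, and 0.0229 in camera with length and GC trends taken out). With those trends taken out, vascular tone had 3 higher and 2 lower genes, endothelium 9 and 0, and mitochondrially encoded genes 1 and 6. Glucocorticoid response genes had 1 lower of 10 (adjusted p = 0.0663) and were called without any of 5 single libraries (lowest adjusted p = 0.0258, without repopulation 4). Choroid plexus genes (0 of 8, adjusted p = 0.535) were called downward without repopulation 4 (adjusted p = 0.00549), striatum genes (0 of 11, adjusted p = 0.278) downward without repopulation 5 (adjusted p = 0.0114) and mitochondrially encoded genes without depletion 4 (adjusted p = 0.0368). Overall counts were 1398 genes higher and 1649 lower, 331 and 13 of them by at least 1 log2 unit. With the length and GC trends taken out, 890 were higher and 1735 lower, of which 801 and 1225 were called both ways.

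**Figure D3:**
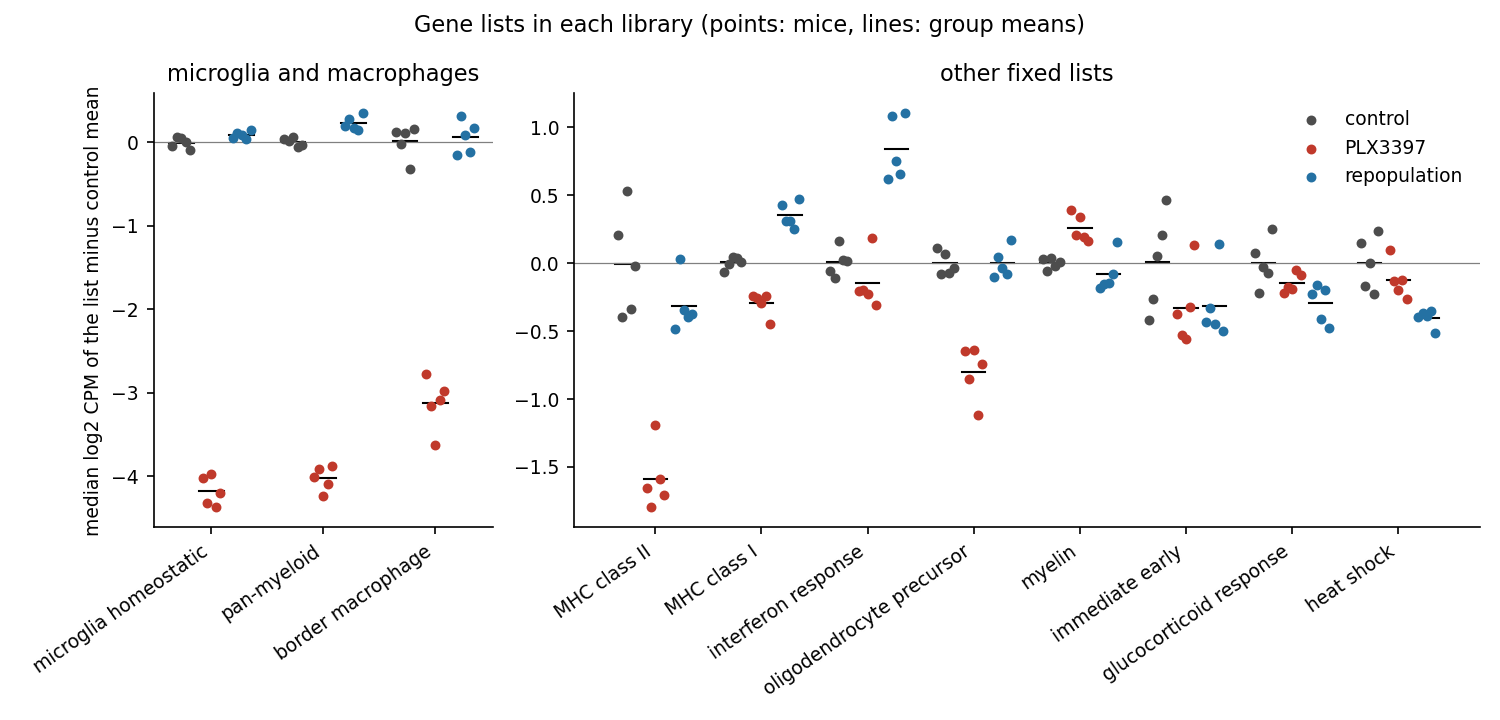
Median log2 CPM of each list's genes less the control mean, for 11 lists in each of the 15 libraries, with points for mice and lines for group means. The interferon score is 0.844 on average after repopulation against 0.00887 in control, and the precursor score is -0.80 on PLX3397.

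The third comparison, repopulation against control, asks whether the cortex with returned microglia matched the untreated one. Homeostatic genes stood at 106% ± 3.34 and pan-myeloid genes at 117% ± 6.99 of the control mean (SD, n = 5, exact permutation p = 0.0476 and 0.00794). These are medians over genes, and with the mean of log2 ratios homeostatic genes stood below control, at 93.3% (84.7 to 97.0% per library). Csf1r was higher than in control (105 against 84.9 CPM, 0.31, adjusted p = 5.1e-05), while Cx3cr1 (0.10, adjusted p = 0.258), P2ry12 (0.14, adjusted p = 0.0783) and Tmem119 (0.03, adjusted p = 0.815) were not called. Entpd1 was at 13.6 ± 0.961 against 13.7 ± 0.557 CPM (-0.01, edgeR adjusted p = 0.943, exact permutation p = 0.873). Of 34 pan-myeloid genes 14 rose and 0 fell (14 and 0 adjusted over the list alone), among them Ctss from 31.5 ± 2.66 to 49.1 ± 4.39 CPM (0.64, adjusted p = 9.26e-06) and Ptprc, the leukocyte phosphatase CD45 (0.87). Mpeg1, outside the list, rose from 25.5 ± 2.12 to 45.2 ± 2.52 CPM (0.82, adjusted p = 3.73e-07). Of 17 homeostatic genes 3 rose and 2 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.96). Fcrls remained below control at 9.12 ± 0.932 CPM, 50.7% of the control mean (-0.98, adjusted p = 6.08e-07), as did Crybb1 (-1.16, adjusted p = 3.6e-05). In the activation list, 4 of 15 genes rose and 3 fell (4 and 3 adjusted over the list alone, adjusted p = 0.81), with Itgax (1.79) and the fungal receptor gene Clec7a (1.43) higher and the fatty acid binding protein gene Fabp5 (-0.21) lower. Of 6 border macrophage genes 0 were called (0 adjusted over the list alone, adjusted p = 0.96), and H2-Ab1 (-1.26) was the 1 class II gene of 5 below control (adjusted p = 0.364 for the list).

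Interferon response genes were the called list furthest above control. Of 26 genes 23 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 fold change of 0.89 and a score above every control in all 5 libraries. Ifit3 rose from 5.24 ± 0.651 to 11.5 ± 1.86 CPM (1.13, adjusted p = 4.86e-07) and Irf7, a master regulator of type I interferon, by 1.42. Oasl2 (1.30), Ifit3b (1.19) and Ifit1 (1.15) rose too, as did Ddx60 (1.75, adjusted p = 1.48e-05), a helicase of antiviral sensing, and Lgals3bp (1.53), from 10.9 ± 0.818 to 31.8 ± 7.71 CPM. Of 10 MHC class I genes 5 rose (5 adjusted over the list alone), with H2-D1 (0.52), B2m (0.34) and the peptide transporter gene Tap1 (0.74). C4b stayed above control (0.80, adjusted p = 0.00031) and the chemokine gene Cxcl10 rose (1.48, adjusted p = 0.00311) in the reactive astrocyte list, which was not called (2 higher and 2 lower of 14, adjusted p = 0.81). Camera called the interferon (adjusted p = 7.6e-12), MHC class I (0.00811) and pan-myeloid (0.00811) lists upward. None of the 3 calls held with an estimated correlation (adjusted p = 0.313, 0.471 and 0.313). Fry called all 3 lists (adjusted p = 0.000131, 0.00104 and 0.00104). In the exact permutation test of list scores each had p = 0.00794, the smallest that 252 splits allow, and its adjusted p of 0.0508 over 32 lists therefore settles none of them.

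Some genes of stress and activity lists fell below control. Of 6 heat shock genes 4 fell (5 adjusted over the list alone), among them Hspa8 from 1087 ± 124 to 771 ± 32.2 CPM (-0.50, adjusted p = 0.000751), the co-chaperone gene Dnajb1 (-0.32) and Hspa1a (-0.64). Of 10 glucocorticoid response genes 6 fell (6 adjusted over the list alone), led by Cdkn1a (-0.41), the leucine zipper gene Tsc22d3 (-0.50) and Map3k6 (-0.59), and of 18 immediate early genes 5 fell (5 adjusted over the list alone), led by Nptx2 (-0.36), Bdnf (-0.42) and Nr4a3 (-0.69). Camera called the 3 lists downward (adjusted p = 0.0221, 0.0181 and 0.00811). With an estimated correlation each had an adjusted p of 0.886, and each call was lost without control 5 (adjusted p = 0.0695 for each). Fry called the heat shock and glucocorticoid response lists (adjusted p = 0.0268 and 0.0299) and not immediate early genes (adjusted p = 0.0621). In the exact permutation test of list scores, immediate early and glucocorticoid response genes were not called (adjusted p = 0.271 and 0.0952), and heat shock genes were at the smallest possible p (adjusted p = 0.0508). The heat shock call was also lost without control 1 and repopulation 4 together (adjusted p = 0.0577). Other large decreases were the small heat shock gene Hspb1 (-1.06), the melanosome adaptor gene Mlph (-0.98) and Serinc2 (-0.87). Lcn2, a secreted siderophore-binding protein, was at 0.153 against 2.60 ± 3.73 CPM, a call (adjusted p = 0.0319) that was lost when any of 7 single libraries was left out (up to 0.0858, without control 5) and in limma voom (0.268).

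Among the other lists none was called in this comparison. Inhibitory neurons had 3 higher and 6 lower genes of 12 (3 and 7 adjusted over the list alone, adjusted p = 0.364, and exact permutation p = 0.00794 for list scores of -0.152 against -0.012, adjusted p = 0.0508), with the neuropeptide gene Cck from 184 ± 6.33 to 130 ± 5.58 CPM (-0.50, adjusted p = 9.13e-07), Pvalb (-0.53) lower and Reln (0.39), an extracellular guidance protein, higher. Adk, the kinase that clears adenosine, fell from 40.2 ± 1.67 to 32.2 ± 0.429 CPM (-0.32, adjusted p = 3.23e-05) in the purinergic list (1 higher and 2 lower of 23, 0 and 1 adjusted over the list alone, adjusted p = 0.96, downward while the median was 0.03). Nt5e, at 10.3 ± 1.9 CPM, was called higher (0.31, adjusted p = 0.0498), which was lost when any of 11 single libraries was left out (up to 0.156, without repopulation 2) and with the length and GC trends taken out (adjusted p = 0.168). Adora1 (-0.10, adjusted p = 0.173) and Adora2a (-0.07, adjusted p = 0.836) were not called. Vascular tone had 3 higher and 5 lower of 26 (3 and 5 adjusted over the list alone, adjusted p = 0.81), with the potassium channel gene Kcnj8 lower (-0.67, adjusted p = 0.00431). Smooth muscle had 1 and 1 of 10 (adjusted p = 0.834), with Myh11, the smooth muscle myosin, higher (0.36). Pericytes had 2 and 2 of 12 (adjusted p = 0.834) and endothelium 4 and 5 of 18 (adjusted p = 0.81), with Slco1a4 higher (0.29) and Ly6c1 lower (-0.49). Astrocytes had 1 higher and 6 lower of 15 (adjusted p = 0.304), among them Aldoc, a glycolytic enzyme (-0.30). Precursors had 1 higher of 11 (0 adjusted over the list alone, adjusted p = 0.957, upward while the median was -0.07), myelin 3 lower of 15 (adjusted p = 0.364, and 0.0164 without repopulation 5), including Mbp (-0.21). Synapses had 3 higher and 1 lower of 11 (adjusted p = 0.428), with the scaffold gene Pclo higher (0.36, adjusted p = 5e-07). Choroid plexus genes had a median of 1.53 (0 of 8, adjusted p = 0.486), with a score of 3.24 in repopulation 4 against at most 0.266 in the other 4 libraries. Hippocampus genes (0 of 5) were at -0.35 (adjusted p = 0.96, upward), and striatum genes had 0 of 11 called (adjusted p = 0.81). Adjusted over the list alone, the counts of endothelium were 4 and 6, of pericytes 3 and 2, and those of smooth muscle, astrocytes, myelin and synapses were the same. With length and GC trends taken out, higher and lower genes were 2 and 3 for synapses, 3 and 1 for endothelium, 0 and 1 for pericytes, 1 and 0 for smooth muscle, 1 and 5 for inhibitory neurons, 2 and 3 for vascular tone, 0 and 1 for excitatory neurons, 4 and 1 for microglia activation and 2 and 3 for cholesterol biosynthesis. Astrocytes, with 0 and 6, were then called downward (camera adjusted p = 0.0423). The proliferation list had 3 lower genes of 27 (0 adjusted over the list alone, adjusted p = 0.121), cholesterol biosynthesis 4 higher and 4 lower of 18 (4 and 4, adjusted p = 0.994) and excitatory neurons 3 lower of 9 (3, adjusted p = 0.364).

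Small changes were most frequent here, with 2548 genes higher and 2797 lower than in control, 64 and 25 of them by at least 1 log2 unit, and medians of 0.24 in both directions. The smallest adjusted p-values outside the lists included the kinase gene Tnik (0.46), Dmxl2 (0.39) and the deubiquitinase gene Usp34 (0.41) among higher genes. Among lower genes they included the autophagy genes Map1lc3a (-0.42) and Gabarapl1 (-0.33), the calcium uniporter subunit gene Smdt1 (-0.54), Stmn3 (-0.41) and the glycolytic gene Tpi1 (-0.38). The slope on exon length was 0.0523 ± 0.005 per doubling after repopulation against -0.0494 ± 0.0137 in control (exact permutation p = 0.00794), and the 20% of genes with the shortest and the 20% with the longest exons had median log2 fold changes of -0.09 and 0.11. With the length and GC trends taken out, 1567 genes were higher and 2404 lower, of which 1322 and 1700 were called both ways.

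Genes called on PLX3397 were then followed into repopulation. Of the 1533 genes lower on PLX3397, 632 were called higher again against PLX3397, 635 were still lower than control, 118 stood above control and 288 were called in neither later comparison. Of the 1505 higher genes, 129 were called lower again, 1101 were still higher than control, 4 stood below it and 278 were called in neither later comparison. The classes overlap. For example, 22 of the lower genes were both called higher again and still lower than control, and 3 of the higher genes were both called lower again and still higher. With length and GC trends taken out, the genes still changed in the same direction numbered 924 instead of 1736. These counts share libraries. When genes were called with 3 PLX3397 libraries and tested against the other 2, a median over 10 splits of 36.1% of lower and 3.55% of higher genes came back. When called against 3 controls and tested against the other 2, a median of 23.4% and 53.7% were changed the same way after repopulation. Tests against 2 libraries have less power than those against 5, so these shares are not on the scale of the counts above. The numbers of genes changed in the same direction in both comparisons with control, 1101 higher and 635 lower, stand beside 208.8 and 233.4 for independent lists. Simulated unchanged groups sharing the controls hold hardly any called genes, so their 0 shared calls give no measure for these counts. With separate controls for each comparison, 490.2 were higher in both and 229.7 lower in both on average over 20 fits, against 77.92 and 99.99 for independent lists. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.0255 (SE 0.0118 from leaving out single libraries), with Pearson's r of 0.173 and a Spearman correlation of 0.549. Simulated unchanged groups gave a covariance of 0.0129 (0.0123 to 0.0139 over 20 simulations), with correlations of 0.491 and 0.443. Their genes were drawn independently, without the trends that real libraries share, so this range is likely too narrow. They also hold none of the large changes on PLX3397, so their correlations are not on the scale of the observed ones. Split controls gave a covariance of 0.0110 (0.00565 to 0.0149 over 20 fits), with correlations of 0.0666 and 0.325.

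**Figure D4:**
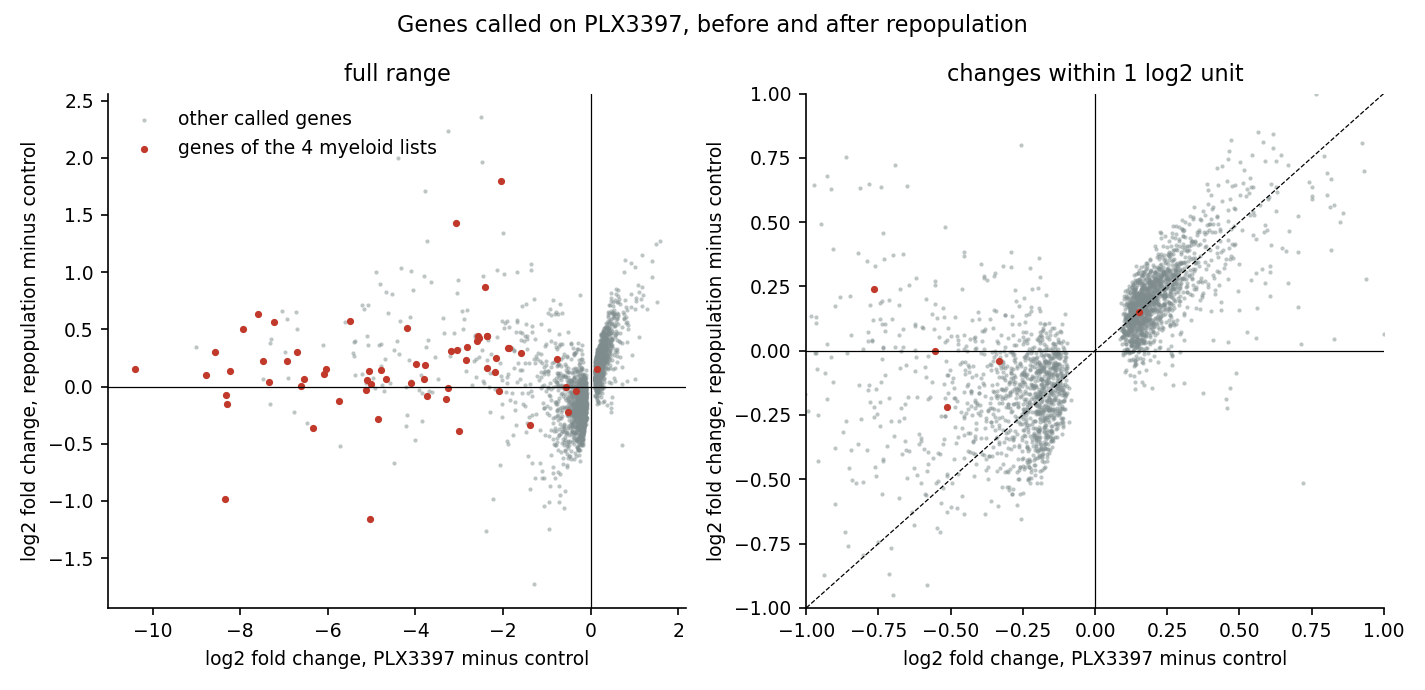
Log2 fold changes against control of the genes called on PLX3397, on PLX3397 (horizontal axis) and after repopulation (vertical axis), over the full range (left) and within 1 log2 unit (right, with the dashed line of equal change), with red points for genes of the 4 microglial and macrophage lists. Of the higher genes, 1101 of 1505 were called higher after repopulation too, with the same controls and before length and GC trends are taken out (53.7% with separate controls). A set of 117 genes fell to under 25% of a control level of at least 1 CPM. They lie between -1.26 and 1.01 on the vertical axis, with 32 called above control and 4 below.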

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

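The measure of how far a library lies from its group was fixed in advance, while the genes it was applied to, the splits of libraries and most tests of explanations below were chosen only after results were seen. In each group of 5 mice, the highest or lowest library was flagged when its gap to the nearest other library, divided by the range of the group, passed Dixon's 95% critical value. Of 507 groups of values tested, 44 were flagged, where chance flags about 1 in 20, or 25.4. The groups share libraries and many genes vary together, so the flags are not independent. Depletion 5 held 8 flags, and control 5, repopulation 4 and repopulation 5 held 5 each.

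Depth and composition gave 3 flags. Control 1 had 48.6 M counts against 24.3 to 30.8 M in the other controls, depletion 5 had 23.4 M against 28.3 to 29.5 M, and mitochondrial genes took 4.43% of counts in control 3 against 4.13 to 4.21%. Among list scores, in log2 units from the control mean, repopulation 4 stood far from its group in choroid plexus genes (3.24 against -0.558 to 0.266) and immediate early genes (0.14 against -0.498 to -0.332), and its Ttr was at 480 CPM against 1.52 to 4.07. Hippocampus scores were high in control 1 (1.6 against at most -0.249) and depletion 2 (1.61 against at most -0.00883). Repopulation 1 was high in erythroid genes (0.994 against at most -2.14) and circadian genes (0.136 against at most -0.0503), and repopulation 2 in MHC class II genes (0.0305 against at most -0.346). Depletion 4 was high in interferon response genes (0.185 against at most -0.196). Depletion 5 was low in MHC class I genes (-0.448 against at least -0.294) and smooth muscle genes (-0.367 against at least -0.131), and repopulation 5 was high in smooth muscle genes (0.0595) and low in heat shock genes (-0.515).

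Single genes gave 29 flags, in CPM. On PLX3397, Csf1r was high in depletion 1 (0.427 against at most 0.176) with Gucy1b3 low (195), Il1a was high in depletion 3 (0.279), and Stab1 (3.59) and Cd74 (1.71) were high in depletion 4. In depletion 5, Tmem119 (0.731), B2m (37.5), Mal (249) and Fth1 (1180) were low and Usp34 (218) was high. After repopulation, H2-Aa (1.8) and Ccl6 (0.984) were high in repopulation 2, Cspg4 (28.9) in repopulation 3 and Thbs4 (12.4) in repopulation 4, where P2ry12 was low (24.9). Laptm5 (33.2), Ednrb (53.8) and Tspan2 (142) were high in repopulation 5. In controls, Lcn2 was high in control 5 (9.06 against at most 2.38) with Tgfb1 (6.42), while Itm2a (22.2), Cdh2 (89.8) and Lgals3bp (9.53) were low there. Cspg4 was high in control 1 (27.3), Mag (191) and Reln (117) in control 3 and Fam214a (46.6) in control 4, where Mrc1 was low (3.55).

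The first pattern weighed is the large number of small gene changes against control. The called genes that moved by under 0.5 log2 units numbered 2469 on PLX3397 and 4790 after repopulation. With length and GC trends taken out, 44.6% and 53.3% of them were still called in the same direction. Without control 1, the deepest library, the shares were 72.3% and 82.8%. Neither that library nor the trend as fitted is therefore the whole cause, while a trend stays open for the genes it removed. Outside the myeloid lists, the fit left Spearman correlations of fold change with length and GC of -0.0267 and 0.0405 on PLX3397. After repopulation they were 0.0493 and 0.0068, so a remainder of the trend is not excluded. The real grouping was the only 1 of 60 splits, drawn from 126 possible ones, with as many called genes in each comparison (3038, 5345 and 3047 genes, against at most 678, 1 and 364). A share of 1 in 60 is the smallest these splits can give, and it concerns the count of genes and no single gene. Mixed splits take the treatment difference into the spread within groups, so their low counts do not measure false calls. For the number of called lists, 11, 27 and 4 of 60 splits called as many (13, 6 and 16 lists, against up to 17, 11 and 19). Some of these splits keep 4 libraries of a group together and with them much of the treatment difference, so they cannot decide whether the list counts arose by chance. The numbers in the column names run group by group, with 0 libraries inside another group's run, so an order of preparation that follows the groups could produce small changes and cannot be told from the treatment.

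The second pattern is the interferon response above control after repopulation. An even rise of myeloid RNA is excluded as the whole cause. The lowest interferon score was 0.619 against a highest pan-myeloid score of 0.348, in a comparison chosen after the scores were seen. Single pan-myeloid genes ran from -0.219 to 0.874, so an uneven rise of myeloid RNA stays open. A length and GC trend is excluded as the whole cause, because the median was 0.896 without it and 0.892 with it. All 5 repopulation libraries lay above every control, which a shared housing or infection of these mice would give as well as the treatment, so the data cannot tell them apart. If returned microglia were the source, members that fell more on PLX3397 might rise more after repopulation, a prediction written before the test. The Spearman correlation was -0.029 over 26 members (Pearson -0.337), but the fold changes share their controls, which raises such a correlation with no effect at all, so the test is void and this source stays open.

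The third pattern is the opposite move of oligodendrocyte precursor and myelin genes on PLX3397. A larger share of white matter, which also holds precursors, would lower neuronal genes at least as far, but the lowest excitatory neuron score on PLX3397 was -0.199 against a highest precursor score of -0.642, so it is excluded as the whole cause for precursors, in a comparison chosen after the scores were seen. For myelin it stays open, since the lowest excitatory neuron score of -0.199 lies within the control range, whose lowest was -0.208. Taking out length and GC trends left the precursor median at -0.664 (from -0.706) and the myelin median at 0.281 (from 0.268). The precursor median was -0.065 after the food was withdrawn, but withdrawal ends the drug and restores microglia together, so a direct effect of PLX3397 on precursors could not be told from the loss of microglia. A fall of newly formed oligodendrocyte genes with the precursor genes was predicted before the test. These genes did not fall as a list, with a median of -0.028 over 11 genes (exact permutation p = 0.77). Of them, 2 genes, Enpp6 and Bmp4, are also in the precursor list. Bulk RNA of these genes does not count cells, so a fall in newly formed oligodendrocytes themselves stays open.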

How the results depend on the processing

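The length and GC correction, the fit without control 1 and repopulation 4, the exact permutation test of list scores and the overlap outside the myeloid lists were chosen after the data were seen, and the other alternatives before. Of 265 calls of named genes, 204 held under every setting, 41 were lost with the length and GC correction, 36 in at least 1 fit without a single library and 0 in DESeq2, which gave no adjusted p for 3, while 38 uncalled results passed in some setting. The exception in direction was Shank3 in repopulation against PLX3397, at -0.003 with the correction. With the correction the counts were 1567 higher after repopulation against control, 890 higher against PLX3397 and 924 still changed, against 2548, 1398 and 1736. DESeq2 gave 1650 and 1627, 2703 and 2900, and 1500 and 1793 genes in the 3 comparisons. On the simulated counts it made 26, 22 and 34 false calls against 12, 13 and 15 in edgeR, so holding in DESeq2 is a mild check. Fits of only the groups compared gave 1272 and 1126, 2706 and 3058, and 1360 and 1488, with 1421 still changed, and 1 surrogate variable gave 1786 and 1821, 2889 and 3009, and 1661 and 1892, with 2152 still changed. Without single libraries, higher and lower genes ran from 1155 to 1577 and 1223 to 1656 on PLX3397, 2079 to 2563 and 2476 to 2947 after repopulation, and 1082 to 1708 and 1234 to 1994 between the treated groups, returned genes from 605 to 787 and still changed genes from 1261 to 1914. Entpd1 ran from -0.91 to -0.84, -0.05 to 0.02 and 0.81 to 0.89. Called lists numbered 5, 0 and 8 with an estimated correlation, 10, 0 and 16 in the exact permutation test (where in the comparison with 0 only 5 lists reached the smallest possible p), and 13 to 17, 3 (without control 5) to 7 and 15 to 18 without single libraries. With the mean of log2 ratios instead of the median, homeostatic genes stood at 4.70% on PLX3397 and 93.3% after repopulation, and without single libraries at 3.09 to 3.44% and 103.4 to 107.6%, pan-myeloid genes at 4.64 to 5.02% and 114.3 to 118.6%. The covariance of effects was 0.0110 with split controls and 0.0224 to 0.0351 without single libraries. For the changed values the cause was not tested. Replicate numbers carry no pairing (correlations -0.131 to 0.103), and with them as a block 1376 and 1456, 2410 and 2670, and 1312 and 1489 genes, 15, 6 and 15 lists, 705 returned and 1623 still changed genes were called. Of the named calls, 10 were not made with the block. The block called the interferon response (0.0484) and proliferation (0.0415) on PLX3397 and not astrocytes between the treated groups (0.0663). Depth limits genes near or below 1 CPM.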

Other observations

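The gene families and the set of depleted genes below were chosen only after results were seen. Of 117 genes at 1 CPM or more in control that fell to under 25% of control on PLX3397, all 117 rose again after repopulation, to a median of 117% of control (range 41.9 to 202). They were chosen on the PLX3397 libraries they are then compared with, which favours a rise. Against control, 32 of them were then called higher, 4 lower and 81 neither. The lower ones were H2-Ab1 (41.9%), Crybb1 (44.6%), the melanosome adaptor gene Mlph (50.4%) and Fcrls (50.7%). Among the higher ones were Cd180, a receptor of the Toll-like family (202%, edgeR adjusted p = 0.000261), the checkpoint receptor gene Lag3 (199%, adjusted p = 7.43e-06), the metal transporter gene Slc11a1 (185%, adjusted p = 2.46e-05) and the myosin gene Myo1f (163%). Outside the fixed lists, 66 of the 117 genes had a median of 122%.

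Gene families were counted by symbol in repopulation against control, where 15.2% of all tested genes were called lower and 13.9% higher. Members were taken by the start of the symbol alone, so a family can hold other genes, such as kinases named after a ribosomal protein among the cytosolic ribosomal proteins. Of 101 genes with symbols of the cytosolic ribosomal protein type, 77 were called lower and 3 higher (median log2 fold change -0.37). Of 46 NADH dehydrogenase genes 40 were lower (-0.28), of 16 ATP synthase genes 13 (-0.30), of 78 mitochondrial ribosomal protein genes 51 (-0.22) and of 38 proteasome genes 28 (-0.17). Of 68 protocadherin genes, which give neurons their surface identity, 30 were higher and 0 lower (0.24), and of 371 zinc finger genes 85 were higher and 13 lower (0.10). With length and GC trends taken out, the counts were 70 lower and 1 higher for cytosolic ribosomal proteins (-0.26), 22 lower for NADH dehydrogenase (-0.15), 13 lower for ATP synthase (-0.20), 29 lower and 2 higher for mitochondrial ribosomal proteins (-0.13) and 19 lower for the proteasome (-0.12). They were 25 higher and 1 lower for protocadherins (0.22) and 51 higher and 17 lower for zinc fingers (0.06). The fixed list of mitochondrially encoded genes had 1 higher and 1 lower of 11 in this comparison (camera adjusted p = 0.392). Its score was -0.0906 after repopulation against -0.00474 in control (exact permutation p = 0.0159, adjusted p = 0.0847). Mitochondrial genes took 3.82 to 4.017% of counts after repopulation against 4.128 to 4.426% in control. These counts are of genes that vary together and carry no test of the family.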
